A study of Mus musculus with 3 samples.

How the data were processed

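Total RNA depleted of ribosomal RNA from the nuclear fraction of Lipid A-treated macrophages was sequenced by the submitters in 3 libraries, 1 per biological replicate. The labels give a size range of 250 to 400 nucleotides. Each library came with a gene table, a transcript table and a second transcript table made by another method. Per the file headers, the first kind of table holds expected counts, that is reads divided among genes by a model, and TPM as deposited by the authors, with the column names that RSEM writes. The upper bound of the credibility interval of each TPM value, deposited by the authors, was treated as a score and entered no comparison. The second table has the column names that kallisto writes and holds estimated counts and TPM, per the file headers. The notes deposited with each library name the mouse build mm10 and the GENCODE annotation M21. The program versions are not given in the sources used here. All 55536 genes of that annotation were found in the gene tables, and gene names, types and coordinates (GRCm38) came from it.

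Rows that name no gene were kept out of library sizes and tests. They were the phiX spike-in, 96 ERCC spike-ins and 26248 numbered rows. The phiX row held 1.24% of all expected counts in replicate 1, 0.371% in replicate 2 and 0.0640% in replicate 3. ERCC rows held 0 counts and the numbered rows 34, 74 and 35 counts. Annotated genes held 18516063, 17345644 and 20947006 expected counts in replicates 1 to 3, so 3 counts, the number that a count of 0 allows, correspond to 0.162, 0.173 and 0.143 CPM. Such floors cover counting error only. The second table held 1.36, 1.75 and 1.46 times as many estimated counts. Mean fragment lengths, taken from the gap between length and effective length of long genes, were 228, 222 and 187 nucleotides, all below the size range in the labels. A chi-square comparison of counts over genes gave 90.2, 154 and 142 per degree of freedom for the pairs 1 and 2, 1 and 3, and 2 and 3, so no pair agreed within sampling noise as copies of the same library would; this does not show that they are biological replicates, which rests on the labels. Separate biosamples are recorded but 1 donor entry for all, so the spread between replicates may be technical.

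Gene lists and markers of other cell types were fixed before the data were examined, as were the list differences, the shares, the spread of lists, the distances between libraries, the comparison of tables and most of their alternatives. The deviation of each library by list, the split of retained-intron shares by list and the tests named as such in the closing section were chosen later. For each library the median over a list of log2(TPM + 0.1) was taken, and lists were compared by the difference of medians within a library, which cancels library scaling except for genes near the pseudocount. Differences are given as the mean and SD over 3 libraries with a two-sided exact sign-flip permutation test, whose smallest p with 3 libraries is 0.25; 9 such differences were computed, none could pass a threshold, and no adjusted values are given. Fold values are on the log2(TPM + 0.1) scale and understate differences of low genes. Very short RNAs have small effective lengths, which makes their TPM large and imprecise, and TPM between libraries moves with them. Libraries were therefore compared on counts: expected counts were rounded to whole numbers, genes with a mean count of at least 10 were kept, and log2 CPM values were computed with edgeR 4.0.16 and TMM factors of 1.07, 1.02 and 0.921. The common biological coefficient of variation came from edgeR with an intercept-only model. The level or spread of a list was described by its percentile among 10000 random lists of the same size. These were matched on gene length in 10 bins for levels and on expression in 20 bins for spread and for deviations of a library. They were drawn from genes of any type with a mean count of at least 10. A list is called above, below or outside random lists where it lay beyond their central 95%. Percentages of counts used annotated genes as the denominator, where the plan had all rows; the second is among the alternatives. Retained-intron shares used transcript types of the annotation. Gene symbols with more than 1 identifier were taken at the identifier with the highest mean count.

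By their level, the lists stood as follows among random lists matched on gene length. Secondary response genes and 7 of the 9 marker lists were at percentile 0, dendritic cell markers at 0.0300 and endothelial markers at 0.490. These low percentiles follow in part from the draw, since random lists held only genes with a mean count of at least 10. The lists themselves kept members below that count: 14 of 26 secondary response genes and 0 of 6 T cell markers were measured. Proliferation genes were at 10.9, heat shock genes at 52.9 and replication-dependent histone genes at 60.8. Feedback regulators were at 99.7, interferon-stimulated genes and the Tlr4 pathway at 99.99, and the immediate early, early inflammatory, macrophage, nuclear non-coding, ribosomal protein, housekeeping and mitochondrial lists at 100.

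Genes were named by a rule fixed before the data were examined. It took the 4 members of each list with the highest mean TPM and the 2 with the lowest, or the 6 highest and 3 lowest for the immediate early, early inflammatory, feedback, secondary response and macrophage lists. It also took the 10 protein-coding genes with the highest TPM, the 10 genes with the highest share of counts, the 6 with the largest spread between libraries among genes with a mean count of at least 100, and the 4 with the largest ratio between tables each way. A few genes of interest were always named. Only part of these genes are described, and some are not reported here. Other genes are marked as named after their values were seen.

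The edgeR step was tested on simulated counts for 15876 genes in 3 libraries. Coefficients of variation set to 0.2 and 0.4 were recovered as 0.222 and 0.411, and a log2 shift of 2 in 200 genes as 1.98 and 2.08. The median deviation of a list in replicate 3 was tested on simulated counts of 200 genes, without TMM factors. Shifts of 1 and -1 were recovered as 0.93 and -0.94. No shift gave -0.15, close to the lower bound of random lists at -0.16. Genes were drawn independently, so this does not show how wide the range should be for genes that vary together. Alternatives were other pseudocounts, count minimums, means in place of medians, CPM, the second table, DESeq2 1.42.0 size factors, upper quartile scaling, long genes only, other fold thresholds and leaving out each library. GC content was taken from the annotated transcripts for a correction of library deviations on GC content and gene length, with cubic terms. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.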

Results

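RNA was sequenced from the nuclear fraction of mouse bone marrow-derived macrophages, primary phagocytes grown from marrow progenitors, of the C57BL/6J strain. The cells had been exposed for 15 min to 100 ng/ml Lipid A, the part of bacterial lipopolysaccharide that the receptor Tlr4 recognises. Ribosomal RNA was removed before library preparation, so that RNA with and without a poly(A) tail was sampled. The labels give 1 group of 3 biological replicates, with no untreated or later sample among those analysed here, so the values below describe the RNA of the nuclear fraction at this time and not a change caused by Lipid A. The deposited gene tables held 18516063 expected counts in annotated genes for replicate 1, 17345644 for replicate 2 and 20947006 for replicate 3. Replicate 2 was made from 500 ng of RNA and the others from 1 µg. Of 55536 annotated genes, 15876 had a mean expected count of at least 10 over the 3 libraries, among them 11960 of 22028 protein-coding genes and 503 lincRNAs.

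The first comparison asked how abundant the genes that macrophages switch on earliest were in RNA of the nuclear fraction, beside genes of the later, secondary wave. All 3 early-response lists stood far above the secondary response genes in each library. The list named immediate early transcription factors, with genes such as Fos, Junb and Egr1, was 54.9-fold above them, with a log2 difference of list medians of 5.78 ± 1.03 (SD, n = 3). Early inflammatory genes such as Tnf and Cxcl2 were 58.5-fold above (log2 5.87 ± 0.65, SD, n = 3), and feedback regulators such as Zfp36 and Nfkbia 28.4-fold above (log2 4.83 ± 0.57, SD, n = 3). The median member of the immediate early list was at 26.4 ± 10.1 TPM (a length-corrected relative abundance, SD, n = 3), of the early inflammatory list at 27.4 ± 5.65 TPM and of the feedback list at 13.6 ± 4.57 TPM, against 0.382 ± 0.173 TPM for secondary response genes. Such a gap was not particular to early-response lists: interferon-stimulated and Tlr4 pathway genes, described below, were 40.3- and 33.2-fold above secondary response genes.

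In the list named immediate early transcription factors, 28 of 29 genes were measured and 6 reached a mean of 100 TPM. Despite its name, the list also holds genes of other kinds, among them Mcl1 and Gadd45b. Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273), a subunit of the AP-1 transcription factor, was the most abundant at 274 ± 41.1 TPM (SD, n = 3). It was followed by Mcl1, a survival factor of the Bcl-2 family, at 241 ± 16 TPM and by the AP-1 subunit Junb at 229 ± 37.5 TPM. Ier2 was at 114 ± 57.4 TPM, the stress-response gene Gadd45b at 104 ± 59.6 TPM and the zinc finger factor Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984) at 101 ± 64.8 TPM. The lowest members were the orphan receptor Nr4a3 at 0.753 ± 0.654 TPM, Klf4 at 0.750 ± 0.157 TPM and Fosl1, which had 1.39 expected counts in replicate 1 and 0 in the others. Nr4a3 had 5 counts in replicate 1 against 70 and 71 in replicates 2 and 3.

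Early inflammatory genes were led by Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007), the cytokine tumour necrosis factor, at 201 ± 152 TPM (SD, n = 3). The neutrophil chemokine Cxcl2 was at 146 ± 59.9 TPM and the transcription factor Irf1 at 133 ± 85.5 TPM. The monocyte chemokines Ccl7, Ccl3 and Ccl2 were at 114 ± 135, 113 ± 22.7 and 101 ± 102 TPM. The cytokines Il23a and Lif and the chemokine Cxcl3 were the lowest members, at 0.25 ± 0.139, 0.107 ± 0.0416 and 0.270 ± 0.265 TPM. Of the 30 members, 22 had a mean of 10 TPM or more. Feedback regulators were led by Zfp36, an mRNA decay factor, at 348 ± 35.1 TPM and Nfkbia, the inhibitor of NF-κB, at 198 ± 110 TPM. Dusp1, a phosphatase of MAP kinases, was at 163 ± 17.5 TPM, with Rgs1 at 125 ± 25.3, Ier3 at 114 ± 33.4 and Dusp2 at 100.4 ± 51.8 TPM. Socs1 and Spry1, inhibitors of cytokine and growth factor signalling, were at 0.557 ± 0.0379 and 0.0700 ± 0.0265 TPM.

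Secondary response genes were scarce: 14 of 26 were measured and 4 had at most 3 counts in every library. Il18 at 13.3 ± 3.60 TPM and the interleukin subunit gene Ebi3 at 10.9 ± 1.46 TPM were the only members at 10 TPM or more. Next came Irak3 at 7.68 ± 1.56 TPM, the acute phase gene Saa3 at 6.46 ± 7.21, the chemokine Ccl5 at 6.28 ± 3.39 and Acod1, which makes itaconate, at 3.39 ± 1.35 TPM. Il12a had 0 counts in all 3 libraries, which allows up to 3 counts in each. Cxcl9 had 1 count in each library and Csf2 a single count in replicate 3. Another 3 cytokine or effector genes, named after their values were seen, were near this floor as well, with 4, 3 and 16 counts for Il6, 9, 11 and 13 for Il12b and 8, 10 and 3 for Nos2 in replicates 1 to 3. Interferon beta, Ifnb1, had 3, 4 and 7 counts.

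Every library gave the same sign for each of these differences, and the exact two-sided sign-flip permutation test gave p = 0.25 (n = 3), the smallest value that 3 libraries allow. Part of the size of the differences rests on secondary response genes near the detection floor: over members with a mean count of at least 10, the log2 differences were 4.005, 4.02 and 2.92 for the 3 early lists.

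**Figure D1:**
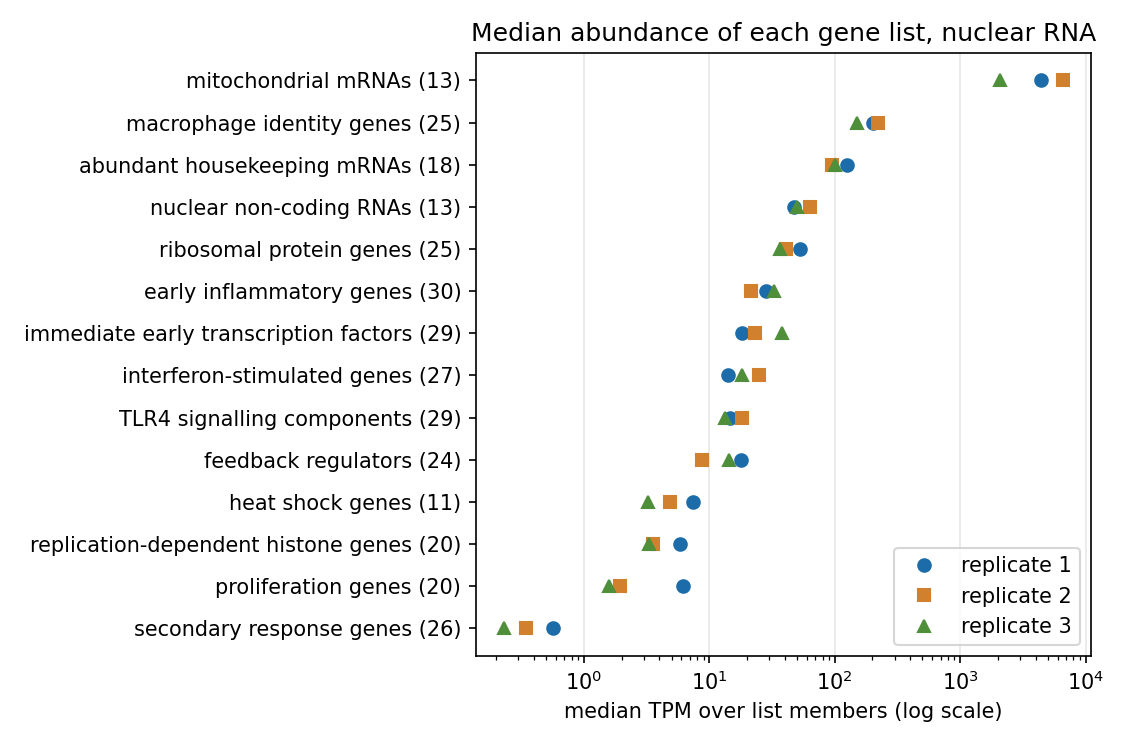
Median TPM over the members of each gene list (x axis, log scale), with 1 point per library and the number of genes in each list in parentheses. Secondary response genes lie lowest in every library, between 0.230 and 0.570 TPM, and mitochondrial mRNAs highest, between 2061 and 6567 TPM.

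Genes that define macrophages, that respond to interferon or that carry the Tlr4 signal were compared next. Macrophage identity genes were the most abundant of these, with a median of 192 ± 37.3 TPM (SD, n = 3), 10.2-fold above interferon-stimulated genes (log2 3.35 ± 0.42, SD, n = 3). The lysosomal protease genes Ctsd and Ctsb were at 2040 ± 219.9 and 1913 ± 353 TPM and the lysozyme gene Lyz2 at 1978 ± 377 TPM. Apoe, the lipid carrier, was at 880.0 ± 210 TPM, the protease Ctss at 639.8 ± 54.3 and Csf1r, the receptor for the growth factor that maintains macrophages, at 406 ± 92.2 TPM. Low in this list, the transcription factor gene Cebpa and the cytoskeletal gene Aif1 were still at 14.2 ± 1.49 and 14.4 ± 1.77 TPM.

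All 27 interferon-stimulated genes were measured, with a median of 19.0 ± 5.45 TPM (SD, n = 3), 40.3-fold above secondary response genes (log2 5.33 ± 0.81, SD, n = 3). Ifi204, a DNA sensor of the interferon-inducible family, was at 103 ± 29.2 TPM, the antiviral synthetase Oas2 at 86.1 ± 27.9 and the interferon signal transducer Stat2 at 69.5 ± 8.51 TPM. The lowest were Ifi44 at 5.98 ± 3.66 and Ifi205 at 4.41 ± 2.05 TPM. These levels coincided with 3 to 7 counts of Ifnb1 per library. All 29 components of the Tlr4 pathway were measured too, 33.2-fold above secondary response genes (log2 5.05 ± 0.52, SD, n = 3). The co-receptor Cd14 was at 270 ± 32.4 TPM, the kinases Ikbke and Tbk1 at 108 ± 8.51 and 44.5 ± 8.46 and the transcription factor Irf3 at 50.7 ± 1.96 TPM. Tlr4 itself was at 25.8 ± 7.54 TPM, its partner Ly96 at 11.49 ± 6.10 and the adaptor Myd88 at 12.5 ± 1.74 TPM, with Tab3 and Tirap the lowest members at 3.34 ± 0.890 and 2.71 ± 0.623 TPM. Each difference had the same sign in the 3 libraries, with p = 0.25 in the exact sign-flip permutation test (n = 3). Over secondary members with a mean count of at least 10, it was 3.34 on the log2 scale for interferon-stimulated genes and 3.06 for the Tlr4 pathway.

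Markers of 9 other cell types were examined to see whether cells other than macrophages contributed RNA. Macrophage identity genes were 1239-fold above these markers (log2 10.28 ± 0.24, SD, n = 3; 8.10 over members with a mean count of at least 10). T cell markers had a median of 0.0150 ± 0.00500 TPM, fibroblast markers 0.0117 ± 0.0126, erythroid markers 0.0150 ± 0.0260 and mast cell and basophil markers 0 TPM in each library. B cell, neutrophil and megakaryocyte markers had medians of 0.115 ± 0.0879, 0.127 ± 0.0416 and 0.160 ± 0.125 TPM, and dendritic cell markers 0.310 ± 0.209 TPM. Endothelial markers had the highest median, 0.768 ± 0.341 TPM, and within them Vwf, which encodes von Willebrand factor, reached 27.0 ± 7.22 TPM with 1778, 2617 and 4233 counts. The other endothelial genes were far lower, with Kdr at 4.23 ± 0.420 TPM and Tie1 and Tek at 0.0167 ± 0.00577 and 0.0267 ± 0.0153 TPM.

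The composition of the libraries was examined because they came from a nuclear fraction. Malat1, a long non-coding RNA of nuclear speckles, took 8.85 ± 0.765% of counts (SD, n = 3), the largest share of any gene, and Neat1, the scaffold of paraspeckles, 0.995 ± 0.0917%. Together they took 9.85 ± 0.734%. The small nuclear RNA Rn7sk, which restrains the elongation factor P-TEFb, took 3.97 ± 1.57% and the RNA subunits of the processing ribonucleases P and MRP, Rpph1 and Rmrp, 0.950 ± 0.418% and 0.739 ± 0.302%. Rmrp has 2 gene identifiers that share reads, so its level is uncertain. Mitochondrially encoded mt-Co1 and mt-Nd5 took 2.61 ± 0.918% and 0.929 ± 0.396%, and the lysosomal genes Psap, Ctsb and Gpnmb 1.20 ± 0.371%, 1.02 ± 0.148% and 0.971 ± 0.0902%. The 10 most abundant genes, which are those named here, held 22.2 ± 0.710% of counts, and protein-coding genes 74.9 ± 3.36%. As a share of TPM, which weights short RNAs, protein-coding genes held 28.2%, the 10 highest genes 53.3%, and Malat1 and Neat1 together 1.84%.

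Mitochondrial genes held 7.29 ± 0.939% of counts (SD, n = 3). This share joined opposite shifts: in replicates 1 to 3 mitochondrial ribosomal RNA held 0.124%, 0.0575% and 3.20%, and mitochondrial mRNAs 6.62%, 8.31% and 3.54%. Mitochondrial RNA is made outside the nucleus, so the fraction did not hold nuclear RNA alone. How much of the other mRNAs came from outside the nucleus was not measured. The median mitochondrial mRNA was 90.0-fold above the median ribosomal protein mRNA (log2 6.49 ± 0.76, SD, n = 3). Reads of several of these mRNAs are shared with nuclear pseudogenes on chromosome 1, which took 1.44 ± 0.646% of counts, so single values such as the 1026 ± 895 TPM of mt-Atp6 are uncertain. Ribosomal protein genes, led by Rpl10 at 130.2 ± 24.5 TPM and Rpl3 at 114 ± 55.3 TPM, were in turn at 0.416 of the level of abundant housekeeping mRNAs (log2 -1.27 ± 0.11, SD, n = 3, but -2.04 in CPM). Among the latter, the ferritin genes Ftl1 and Fth1 were at 950.0 ± 66.0 and 934 ± 174 TPM, Actb at 779.7 ± 302 and Gapdh at 77.6 ± 25.9 TPM. Both differences had 1 sign in all libraries, with p = 0.25 in the exact sign-flip permutation test (n = 3). Xist, the RNA that silences an X chromosome in female cells, was at 287 ± 72.4 TPM, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, named after their values were seen, had 0 counts in every library, which allows up to 3 counts each.

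Transcripts that the annotation classes as retaining an intron took 22.8 ± 1.38% of the counts of genes that have such a transcript (SD, n = 3), with 23.4% in replicate 1, 23.8% in replicate 2 and 21.2% in replicate 3. As a share of TPM the value was 34.2%. The count share is an estimate, because reads in exons common to both kinds of transcript are divided by a model.

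The replicates were then compared with each other, since the labels give them different starting quantities. Early-response genes differed between them by more than matched random lists. By spread over the 3 libraries, interferon-stimulated, proliferation, mitochondrial and ribosomal protein genes did so too, while the remaining lists did not. By the deviation defined next, most of the other lists lay outside random lists in some library. The deviation of a list was the median over its genes of each gene's log2 CPM difference from the mean of the other libraries. In replicate 2 it was log2 -0.74, -0.64 and -0.91 for the immediate early, early inflammatory and feedback lists (0.600, 0.643 and 0.532 of the others). In replicate 3 it was log2 0.94, 0.98 and 0.68 (1.92-, 1.97- and 1.60-fold above the others). Median TPM of a list did not always follow this order. In replicates 1 to 3 it was 18.35, 23.21 and 37.74 for the immediate early list and 17.77, 8.72 and 14.32 for the feedback list. The within-library log2 difference of immediate early from secondary response genes was likewise lowest in replicate 1 (4.78, 5.71 and 6.84). Egr1 was at 0.159 of the other libraries in replicate 2, Tnf at 0.199, Nfkbia at 0.212 and Ier2 at 0.285, whereas Fos was at 0.854 and Rgs1 1.44-fold above. In replicate 3, Irf1, Dusp2 and Gadd45b were 3.45-, 3.31- and 3.44-fold above the others. The central range of random lists matched on expression lay between -0.16 and 0.24 on the log2 scale in these libraries. Of the 79 early-response genes, 18 were among the 352 genes at least 2-fold below both other libraries in replicate 2, where chance gives 1.75, and 14 were among the 246 genes at least 2-fold above both in replicate 3, where chance gives 1.22. The chemokine genes Ccl7 and Ccl2 and Tnf were highest in replicate 1, 6.54-, 4.44- and 3.09-fold above the others.

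**Figure D2:**
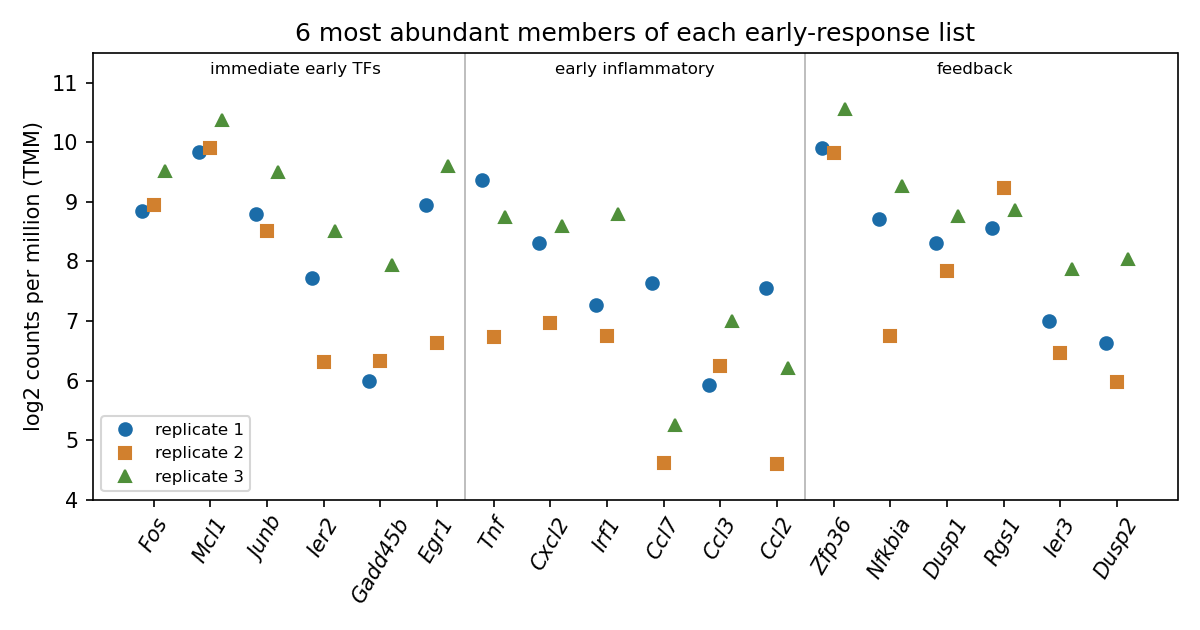
TMM-normalised log2 CPM, a depth-corrected read count (y axis), of the 6 members with the highest mean TPM in each early-response list, with 1 point per library. Tnf, Ccl7 and Ccl2 are highest in replicate 1, Rgs1 in replicate 2 and the other genes in replicate 3.

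Proliferation genes stood apart in replicate 1, where their deviation was log2 1.37 (2.58-fold above the other libraries), and were at 0.508 of the others in replicate 2. Their summed counts were 672, 207 and 231 CPM in replicates 1 to 3, so the low value in replicate 2 follows in part from the rise in replicate 1. The replication licensing genes Mcm6 and Mcm3 were 4.51- and 3.76-fold above, the topoisomerase gene Top2a 2.45-fold and Pcna, the sliding clamp of DNA polymerase, 1.96-fold. Of the 20 members, 13 were among the 771 genes at least 2-fold above both other libraries in replicate 1, where chance gives 0.971. The mitotic genes Ccnb2 and Cdc20, the lowest of the list, were at 0.966 and 1.245 times the others. Replication-dependent histone genes were 1.62-fold above the others in replicate 1 and at 0.588 of them in replicate 2. Interferon-stimulated genes went the other way in replicate 1, at 0.618 of the other libraries, with 23 of 27 below both. In replicate 3 they were 1.43-fold above the others, and macrophage identity genes 1.35-fold above, with 17 of 27 and 19 of 25 genes above both. Ribosomal protein genes and housekeeping mRNAs were 1.34- and 1.16-fold above the others in replicate 1 and at 0.705 and 0.765 of them in replicate 2. Mitochondrial mRNAs were 1.81-fold above in replicate 2 and at 0.539 in replicate 3. Heat shock genes, led by the chaperone Hspa8 at 236 ± 73.6 TPM (SD, n = 3), were 1.46-fold above the others in replicate 1.

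The 6 genes with the largest spread included 3 ribosomal RNA genes. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 were 54.3- and 33.4-fold above the others in replicate 3, where they took 3.20% of counts against 0.124% in replicate 1 and 0.0575% in replicate 2. The ribosomal RNA gene CT010467.1 was 17.1-fold above in replicate 3 and the short RNA Gm25776 10.7-fold above. Dmpk (ENSMUSG00000030409.15, chromosome 7, 19083849 to 19093821), a kinase gene, had 808 counts in replicate 1 and 11 and 13 in replicates 2 and 3. B430305J03Rik had 0 counts in replicate 2 and 395 and 775 in replicates 1 and 3.

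**Figure D3:**
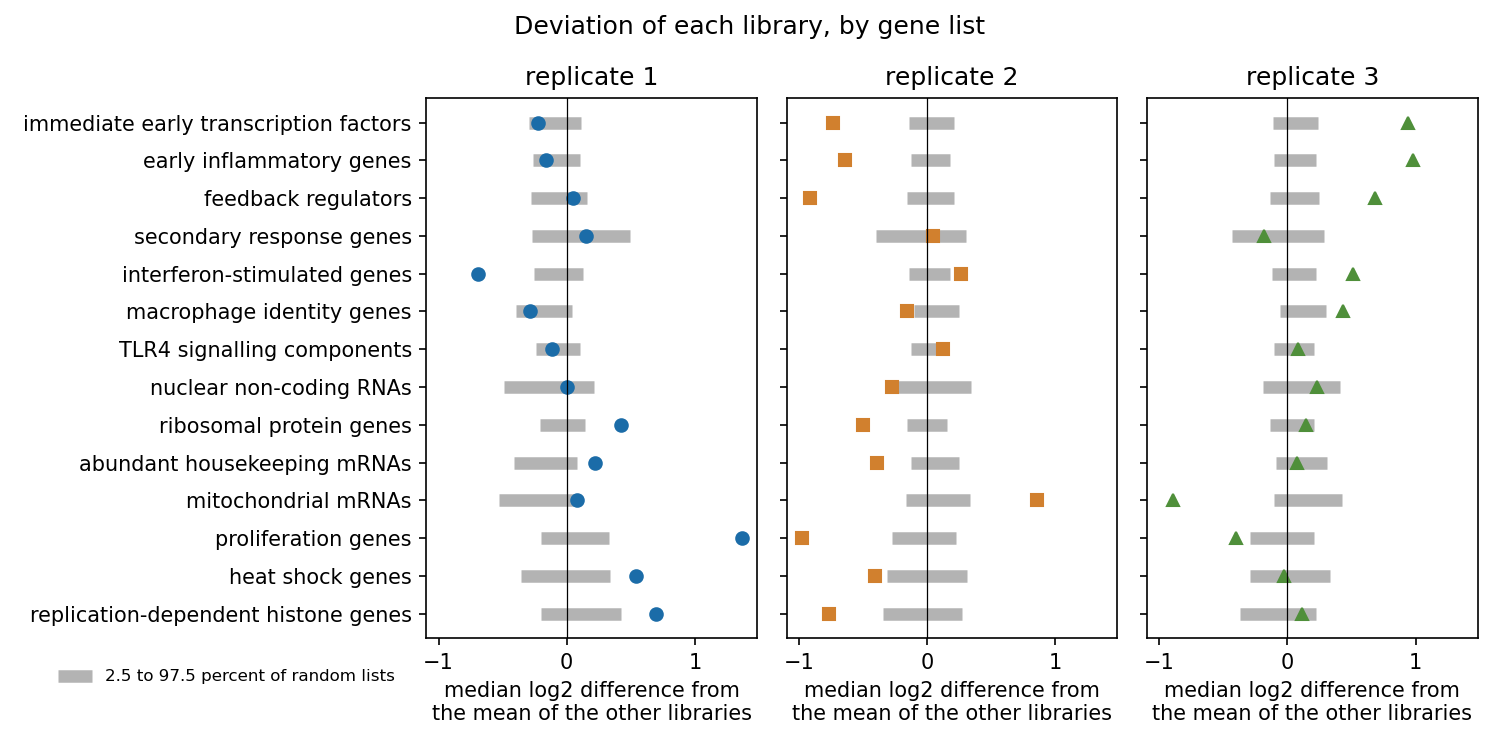
Median log2 difference of each gene list in a library from the mean of the other libraries (x axis), with grey bars for the central 95% of 10000 random lists matched on expression. The early-response lists lie left of the bars in replicate 2 and right of them in replicate 3, and proliferation genes lie right of them in replicate 1.

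Over all measured genes, the biological coefficient of variation from edgeR was 0.315. Replicates 2 and 3 were closest, with a Pearson correlation across genes of 0.968 (Spearman 0.975; genes are not independent replicates) and 1347 of 15876 genes apart by 2-fold or more. Replicates 1 and 2 had r = 0.951 (Spearman 0.960) and 2348 such genes, and replicates 1 and 3 had r = 0.952 (Spearman 0.959) and 2405, so the library of 500 ng was not the one farthest from the rest. The spread of immediate early transcription factors was 0.70 on the log2 scale against 0.28 for matched random lists, a difference of 0.42 that became 0.48 without replicate 1, 0.27 without replicate 2 and 0.29 without replicate 3. Early inflammatory, feedback, interferon-stimulated and proliferation genes had spreads of 0.78, 0.71, 0.62 and 0.82, at the 100th percentile of random lists, whereas Tlr4 pathway genes had 0.20, at the 8.28th percentile. One library against the others allows no test across libraries, and nothing in the labels says that the replicates came from separate animals.

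The series holds a second transcript table per library, which allowed 2 quantifications of the same libraries to be compared. The second held 1.36, 1.75 and 1.46 times as many estimated counts in replicates 1 to 3. The tables therefore did not assign the same set of reads, and the differences are not of method alone. Pseudogenes and small RNAs differed most. The mitochondrial pseudogenes Gm10222, Gm10925 and Gm28438 and the small nucleolar RNA Rnu3a had 6011, 6712, 1868 and 141 TPM in the first table and 0, 1.88, 66.8 and 0 TPM in the second. In the other direction Dcbld2 had 1.27 against 17.1 TPM and Dnah17 0.420 against 8.35 TPM. Snord22 and Gm26447 had the largest positive log2 ratios, 4.48 ± 9.26 and 5.64 ± 10.004 (SD, n = 3), a spread set by libraries in which the first table gave 0 TPM. Their mean TPM over libraries went the other way, with 3297 in the first table against 118 in the second for Snord22 and 4098 against 253 for Gm26447. Over 15869 genes, 8326 differed by 2-fold or more with the same sign in all libraries, 340 higher and 7986 lower in the second table. Most of this count followed the overall scale of replicate 3, where the median log2 ratio was -2.17 against -0.81 in replicate 1 and -0.18 in replicate 2. TPM is relative, and 5 short genes with 0 counts in the first table, the microRNA genes Gm24245, Gm23935 and Gm24270 and the pseudogenes Gm12895 and Gm12896, named after their values were seen, took 65.9%, 35.9% and 87.4% of the second table's TPM in replicates 1 to 3, so the 7986 lower genes reflect in part these few RNAs. Without replicate 3 the count was 2359, and with the ratio centred on its median it was 1926, of which 1763 were higher and 163 lower.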

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

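No test in this part was chosen after the result was seen. Signal appeared in rows outside the annotated genes, above the 3 counts that a count of 0 allows. The phiX spike-in, a bacteriophage genome added to sequencing runs, had 232714 counts in replicate 1, 64618 in replicate 2 and 13411 in replicate 3. The numbered rows with no annotated gene had 34 counts in replicate 1, 74 in replicate 2 and 35 in replicate 3, at most 0.000425% of all rows. No explanation was tested for either.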

How the results depend on the processing

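Chosen after the results were seen were spike-in and numbered rows in the denominator, mitochondrial mRNAs alone and every alternative for the library deviations. Of 163 alternatives to 21 results, 116 stayed within 1 SD between replicates and 47 moved further. The limit was 1.5 times for counts of genes and 1 SD of random lists for list spread and deviations. For the coefficient of variation it was 1 SD of the leave-one-out values. None changed sign, but shares, counts of genes and the coefficient of variation cannot do so. Nor could list differences with a library left out, since all 3 libraries had the same sign. The cause of the moves was not tested, except where low members set the level.

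Secondary response genes near the floor made the list differences depend on the pseudocount and the count minimum. With a pseudocount of 1, the log2 differences from secondary response genes were 4.26 for immediate early, 4.35 for early inflammatory, 3.35 for feedback, 3.83 for interferon-stimulated and 3.56 for Tlr4 pathway genes. Over members with a mean count of at least 10 they were 4.005, 4.02, 2.92, 3.34 and 3.06. The second table gave 4.74, 5.003, 3.80 and 4.28 for the first 4. Means over members gave 4.79 for early inflammatory genes, and CPM 5.66 for feedback and 6.24 for Tlr4 pathway genes. Macrophage identity genes against other-cell markers went from 10.28 to 7.497 with a pseudocount of 1, 11.57 with 0.01, 8.10 over measured members, 9.33 with means, 7.96 in the second table and 10.78 in CPM. Ribosomal protein genes against housekeeping mRNAs were at -1.45 with means and -2.04 in CPM.

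As shares of TPM, Malat1 and Neat1 held 1.84%, the 10 highest genes 53.3%, protein-coding genes 28.2% and retained-intron transcripts 34.2%. The second table gave 7.46%, 19.8%, 70.2% and 26.0%. Among genes with an effective length of at least 300, the first 3 were 11.6%, 18.5% and 80.8%. Mitochondrial mRNAs alone held 6.16%. Leaving out a library gave coefficients of variation from 0.2497 to 0.337, an excess spread of immediate early transcription factors from 0.27 to 0.48, and 2359 to 12272 genes apart between tables. That count was 350 at 4-fold and 1926 after centring. The early-response deviation in replicate 3 was 0.75 after the GC and length correction, and in replicate 2 it was -0.66 after that correction and -0.67 with a mean count of at least 1. No paired analysis was possible because the labels give 1 group. Depth limits secondary response genes and markers of other cells, most of which had few counts.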

Other observations

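The GC and length corrections and the matching on annotated transcripts were set before their results were seen; the tests of scaling, of starting quantity, of other cell types and of the second table were chosen after.

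Retained-intron transcripts were unevenly spread over the gene lists, a split chosen after the data were seen. Among 7094 measured protein-coding genes with such a transcript, the median share of counts was 18.9%. In early inflammatory genes it was 50.8 ± 5.10% (SD over 3 libraries), with 89.9 ± 2.12% in Cd83 and 80.2 ± 4.21% in Cxcl2 but 13.2 ± 1.51% in Irf1 and 5.38 ± 6.42% in Pim1. Feedback regulators had 33.2 ± 3.50%, with 87.9 ± 5.73% in Dusp1 and 2.65 ± 1.04% in Nfkbia, and interferon-stimulated genes 33.2 ± 0.526%. In macrophage identity genes it was 6.58 ± 3.98%, with 0.380 ± 0.0759% in Apoe and 2.17 ± 0.244% in Csf1r but 42.5 ± 7.69% in Aif1 and 60.3 ± 7.03% in Trem2. That low median was within the central range of random lists matched on annotation and expression, 2.12% to 23.9%. Tlr4 pathway genes had 16.7 ± 1.49% and immediate early transcription factors 19.1 ± 3.47%, the latter from 7 genes. Cd83, Pim1 and Trem2 were named after their values were seen.

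The values argue against the number of annotated retained-intron transcripts alone as the source of the high share in early inflammatory genes. The matching did not cover transcript length or shared exons, so other features of the annotation are not excluded. After averaging each gene over libraries, the median share of early inflammatory genes was 52.5%. Lists of random genes with as many annotated retained-intron transcripts and the same expression had a central range of 5.40% to 30.02%. Feedback regulators (33.2%) and interferon-stimulated genes (35.2%) also lay above the central ranges of their matched lists, which ended at 25.8% and 29.3%. Some random lists lie outside such a range by construction. Among their matched lists, the early inflammatory, feedback and interferon-stimulated genes were at percentiles 99.99, 99.44 and 99.57. The method of quantification is not the whole source either. The second table gave 44.9% for early inflammatory genes, against a central range of 8.30% to 32.6% for matched lists. Partly unspliced RNA of genes being transcribed at this time is a candidate explanation; immediate early transcription factors, at 19.1% in a range of 2.03% to 34.9%, bear on it neither way, with only 7 genes. No biological explanation was tested, since the samples analysed here include no unstimulated one.

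The early-response genes, taken as 1 list of 79, lay at -0.78 on the log2 scale in replicate 2, where proliferation (-0.98), histone (-0.77), ribosomal protein (-0.50), heat shock (-0.41), housekeeping (-0.39), nuclear non-coding (-0.27) and macrophage identity (-0.16) genes were also below random lists. Above random lists in replicate 2 were mitochondrial mRNAs (0.85), dendritic cell markers (0.84, from 5 genes with few counts) and interferon-stimulated genes (0.26). In replicate 3 the early-response genes lay at 0.84, where interferon-stimulated (0.51) and macrophage identity (0.43) genes were also above random lists, while mitochondrial mRNAs (-0.89) and proliferation genes (-0.40) were below. Each library is set against the mean of the others, so the deviations of a list are linked and are not separate shifts. Proliferation genes, at 672, 207 and 231 summed CPM in replicates 1 to 3, were low in replicates 2 and 3 in part because replicate 1 was high. The early-response values of -0.78 and 0.84 depend on each other in the same way. Scaling of the library by a common factor cannot set these genes apart from random lists matched on expression, since it moves both alike. The central range of those lists was -0.05 to 0.16 in replicate 3 and -0.07 to 0.13 in replicate 2. Mitochondrial mRNAs, at -0.89 in replicate 3, were chosen after their direction was seen, so they are no separate test of scaling. The GC and length correction took up 19.2% of the variance in replicate 3 and 16.6% in replicate 2. It left 0.75 and -0.66, both outside random lists, so that trend is not the whole source. Replicates 1 and 3 share a starting quantity and still differed by 0.61 in these genes, so the quantity does not account for replicate 3. For replicate 2 it cannot be told apart from anything else in that library, since 1 library had a starting quantity of 500 ng. Also open and not tested are fragment length (187 nucleotides in replicate 3 against 228 and 222), whatever put 3.20% of counts of replicate 3 in mitochondrial ribosomal RNA, and a difference in timing or strength of the stimulation.

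Proliferation genes lay at 1.37 on the log2 scale in replicate 1, where histone (0.70), heat shock (0.54), ribosomal protein (0.42) and housekeeping (0.22) genes were also above random lists. Scaling of the library by a common factor cannot set these genes apart from random lists matched on expression, since it moves both alike. The central range of those lists was -0.19 to 0.32. Interferon-stimulated genes lay at -0.69 there, below random lists, but were chosen after their direction was seen, so they are no separate test of scaling. The tables also argue against cells of the 9 listed other types: summed proliferation genes were 453 CPM above the mean of the other libraries, while the largest such difference of a marker list was 0.822 CPM, in fibroblast markers, and the upper 95% counting bound over all lists was 1.67 CPM. Sequence composition stays undecided, because the GC and length correction, which left 1.35, took up only 0.390% of the variance. Cells of types not listed and a different share of dividing macrophages between cultures may also be involved, and were not tested.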
